A study of Mus musculus with 4 samples.

How the data were processed

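RNA was measured on 4 Affymetrix arrays, each of 1 RNA preparation from erythroblasts (immature red blood cells) of mouse fetal liver at embryonic day 14.5. Per the labels' protocols, cells carrying Ter119, a surface protein of the red cell lineage, were taken from the livers with magnetic beads. RNA bound to protein was then precipitated with a commercial kit, with either an antibody against Cpeb4 or rabbit IgG. Cpeb4 is an RNA-binding protein of the family that binds cytoplasmic polyadenylation elements (CPE) in mRNA. The groups were taken from the sample titles: Cpeb4 immunoprecipitate (IP, 2 biological replicates), IgG precipitate (1 array) and total input RNA (1 array). RNA was converted to biotinylated cRNA for hybridisation, per the labels.

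The deposited values are log2 expression values, 1 per probe set and array. RMA and the affy package are named in the submitters' processing notes, with no version, probe definition or filter given in the sources used here. RMA usually corrects background, equalises the probe distributions of the arrays by quantile normalization and summarises the probes of a set by median polish, but its settings here were not stated. The probe set names are Entrez gene numbers, so each of the 25206 probe sets stands for 1 gene. Symbols came from the array's annotation table, which can be old: 23185 probe sets had 1 gene symbol, 0 had several and 2021 had none there. No symbol was held by more than 1 probe set. No genome build was named, so no coordinates are given, and no transcript sequences were used here.

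Quantile-normalised probes usually leave arrays with alike distributions, but the IgG array was narrower than the others at the level of probe sets: its SD was 1.74, against 2.13 for input and 2.05 and 2.07 for the IP replicates. Median polish can also give exactly equal values on different arrays. Of all probe sets, 23.9% had equal values on both IP arrays (within 1e-09), 18.3% and 19.9% on input and an IP array, and 6.73% on input and IgG. The IP arrays differed at all other probe sets and were counted as 2 replicates.

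Genes were tested when their mean over the 4 arrays reached the 40th percentile of named genes, a log2 value of 3.844, which left 13911 genes. Differences were fitted on the log2 scale with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 3 groups, 1 residual degree of freedom). P-values were adjusted by Benjamini-Hochberg over the tested genes, and a gene passed at an adjusted p below 0.05. "Rose" and "fell" are used of genes that passed this test. With 1 IgG and 1 input array, the spread came from the 2 IP arrays alone, and each control array was assumed to vary like them. Beside the test, genes were counted by size: those at least 2-fold from a control array in both IP replicates. IgG and input, 1 array each, were compared by size only.

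In 3032 tested genes the IP replicates were tied, so their spread was 0 and limma's prior spread became very small (prior SD 0.00621, prior degrees of freedom 0.418). On simulated data with such ties, for IP against IgG over 13911 genes, the limma test called 1492 of 13711 unchanged genes and recovered 17, 25 and 25 of 50 genes changed by 2-, 4- and 8-fold. Without ties it called 2 unchanged genes and recovered 31, 50 and 50 of 50. The size rule called 0 unchanged genes in either case, and with ties recovered 18, 50 and 50 of 50. A further test was therefore added after the data were seen. It used 1 common IP spread per twentieth of expression (SD 0.0663 to 0.201) and a normal distribution, and is called the common-spread test. With simulated ties it called 91 of 13711 unchanged genes and recovered 48, 50 and 50 of 50. The simulations gave all 4 arrays the same normal spread, with an SD of 0.173 taken from the IP replicates. They therefore did not examine whether a control array varies like the IP replicates. The limma test stayed as planned; the counts by size are given first.

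The 28 gene lists were fixed before the data were examined, as were the tests, the alternatives not named as added and the rule for named genes. For each list with at least 3 tested members, the median difference of each IP replicate was placed as a percentile among 10000 random lists matched on mean expression in 20 bins. A list stood apart when both replicates were at or above the 97.5th or at or below the 2.5th percentile. Members past the limma test were counted over all tested genes and adjusted over the list alone. Named genes were, per control, the 10 called genes with the largest rise and the 5 with the largest fall. To these came the 10 genes highest over both controls, the 5 lowest under both, the CPEB family, the 2 highest and 2 lowest members of each list, and the 5 highest and 5 lowest of IgG against input.

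The alternatives were no filter, a 60th percentile filter, quantile normalization of the 4 arrays again, eBayes with trend and robust, both controls as 1 group, an adjusted p below 0.1, 1.5- and 4-fold thresholds, each IP replicate left out, and camera gene set tests with a preset correlation of 0.01 and with an estimated one. Those added after the data were seen were the common-spread test, tied genes left out, a 2-fold minimum beside the adjusted p, each control array left out of the counts over both controls, and the gene lists after quantile normalization again. The estimated correlation rested on 1 residual degree of freedom, and camera then had 0 lists even at an unadjusted p under 0.05 in each comparison. A missing call with it therefore decides nothing about a list. A planned count of CPE motifs in 3' untranslated regions was not run, because it needs transcript sequences. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. The number of arrays limits the precision of every value.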

Results

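Gene expression was measured in RNA that came down with Cpeb4 from Ter119-selected erythroblasts of mouse fetal liver at E14.5, a stage when the liver is the main site of blood formation. There were 2 biological replicates of the Cpeb4 immunoprecipitate (IP), 1 precipitate with rabbit IgG and 1 sample of total input RNA. The IgG array stands for RNA that comes down without the antibody's specificity, and the input array for the RNA at the start. Whether these control arrays came from the same cell preparation as either IP replicate was not stated. The design asks which mRNAs were associated with Cpeb4, that is, which stood higher in the IP than in both controls. All values are deposited log2 expression values, differences are IP minus control on the log2 scale, and 13911 genes were tested. Both controls were single arrays, so differences have no replicate check on the control side.

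The IP replicates were closer to each other than to either control. Across tested genes, which are not independent replicates, the IP replicates correlated with r = 0.992 (rho = 0.987) and their difference had an SD of 0.216. Input and the IP replicates correlated with r = 0.938 and 0.939, and IgG and the IP replicates with r = 0.829 and 0.827. Input and IgG correlated with r = 0.829. The median value over all probe sets was 4.13 for input, 4.49 for IgG, and 4.15 and 4.17 for IP replicates 1 and 2. The 90th percentile was 7.12 on the IgG array, against 8.02 for input and 7.85 and 7.87 for the IP replicates, so the IgG array held a narrower range of values.

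The Cpeb4 transcript itself was modestly higher in the IP than in either control. Its value was 10.91 ± 0.02 in the IP (SD, n = 2), 10.42 in IgG and 10.39 in input. It rose by 0.50 over IgG (1.41-fold, limma adjusted p = 0.0294) and by 0.52 over input (1.44-fold, limma adjusted p = 0.0458), in both replicates. Cpeb2 was 0.81 over IgG and 0.79 over input but did not pass (limma adjusted p = 0.058 and 0.0915). Cpeb2 passed the common-spread test, added after the data were seen, against both. Cpeb3 differed by 0.16 from IgG and by -0.41 from input and passed neither test. Cpeb1 lay below the level needed for testing, with values of 3.07 in input and both IP replicates and 3.61 in IgG. Against input, the median of the 3 tested family members stood at percentiles 93.8 and 94.4 of matched random lists, and against IgG at 62.0 and 62.9. Adjusted over the list alone, 2 of the 3 members rose against each control.

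**Figure D1:**
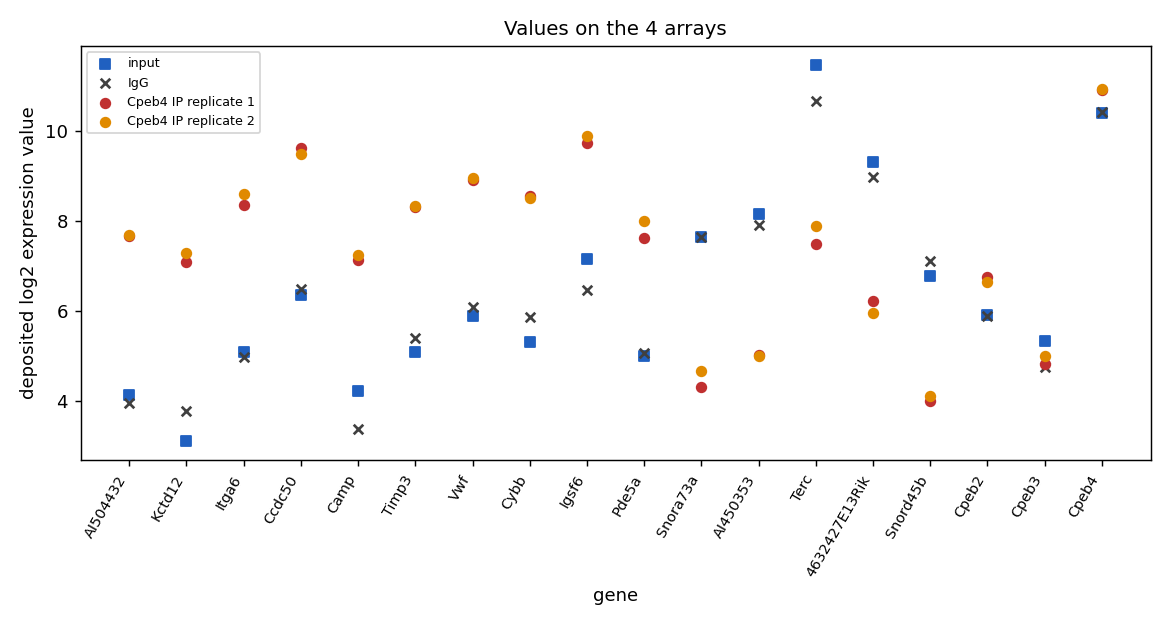
Deposited log2 expression values (y axis) of named genes (x axis) on the input, IgG and Cpeb4 IP arrays, 1 point per array. The first 10 genes are those highest over both controls, the next 5 those lowest under both, and the last 3 the tested CPEB family members; Cpeb4 lay at 10.42 in IgG and 10.39 in input, below both IP replicates.

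Compared with both controls together, the genes that stood out in the IP included AI504432, Kctd12, Camp and Vwf. In both replicates, 346 genes were at least 2-fold higher than IgG and than input, and 70 were at least 2-fold lower than both. AI504432, an expressed sequence, was 13.1-fold over IgG and 11.6-fold over input, from low values of 3.96 and 4.13. Kctd12, a potassium channel tetramerisation domain gene, was 10.7- and 17.1-fold over them, from low control values of 3.78 and 3.10. Camp, the cathelicidin of neutrophil granules, was 14.1- and 7.85-fold higher, also from low values of 3.38 and 4.22, and Vwf, the von Willebrand factor of megakaryocytes and endothelium, 7.15- and 8.29-fold.

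The rest of the 10 highest were Itga6, Ccdc50, Timp3, Cybb, Igsf6 and Pde5a. Cybb, the catalytic subunit of the phagocyte NADPH oxidase, rose by 2.67 over IgG and 3.23 over input. Timp3, a metalloproteinase inhibitor, rose by 2.93 and 3.25. Ccdc50 rose by 3.06 and 3.20 and Igsf6 by 3.33 and 2.65. Itga6, an integrin subunit, rose over IgG by 3.50 (limma adjusted p = 0.0302), and its difference of 3.39 from input missed the threshold (limma adjusted p = 0.0504). Pde5a, a cyclic GMP phosphodiesterase, was 2.73 and 2.81 higher but passed in neither test (limma adjusted p = 0.055 and 0.0831). The 5 lowest under both were Snora73a (-3.15 and -3.16), AI450353 (-2.91 and -3.13), Terc (-2.98 and -3.78), 4632427E13Rik (-2.89 and -3.21) and Snord45b (-3.04 and -2.72), given against IgG and input. Terc is the telomerase RNA, and Snora73a and Snord45b are small nucleolar RNAs. AI450353 and Snord45b fell against both controls, and Snora73a and 4632427E13Rik fell against IgG only by the test, while Terc passed in neither.

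Of the 346 genes, 196 passed the limma test against both controls, and of the 70 genes 22 did. All 346 and all 70 passed the common-spread test, which adds no support. Its smallest called difference was 0.18 against IgG and 0.19 against input, so genes at least 2-fold apart had to pass. Without IP replicate 1 or 2 in turn, the lower set numbered 107 to 111. Leaving out the IgG array gave 562 higher and 721 lower genes, and leaving out the input array 2588 and 868. With IgG and input fitted as 1 group, limma called 0 genes (1112 at an unadjusted p under 0.05). The spread in that fit includes the difference between IgG and input. By the limma test alone, 690 genes rose and 294 fell against both controls. If the 2 size rules were independent, 104.6 genes would be expected above both. The 2 rules share the IP arrays, so ratios that share no array were also set against each other. Genes at least 2-fold up in IP replicate 1 over IgG and in IP replicate 2 over input numbered 398, against 136.4 expected from independent lists. With the replicates exchanged the number was 398, against 133.2. At least 2-fold down, the numbers were 95 against 66.94 and 94 against 72.77. The IP replicates correlated with r = 0.992, so both ratios still carry the same IP profile. An excess over independent lists is thus no proof of association. These pairs of ratios correlated across genes with r = 0.225 (rho = 0.126) and r = 0.212 (rho = 0.106).

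**Figure D2:**
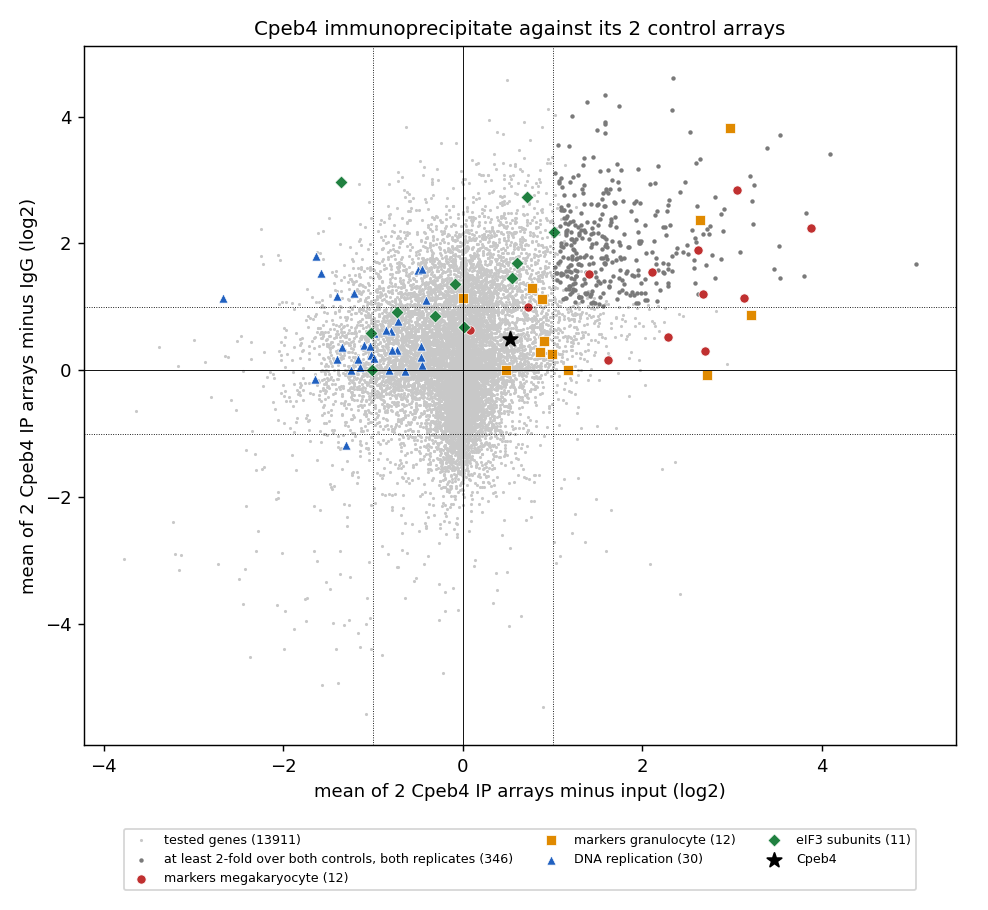
Mean of the 2 Cpeb4 IP arrays minus input (x axis, log2) and minus IgG (y axis, log2), 1 point per tested gene, with dotted lines at 2-fold. Dark grey points are the 346 genes at least 2-fold over both controls in both replicates, and coloured points are members of 4 gene lists; megakaryocyte markers lay mostly to the right, DNA replication genes to the left and eIF3 subunits mostly above 0 on the y axis.

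Compared with IgG, the IP held more RNA of the subunits of eIF3, the largest translation initiation complex, and less of replication-dependent histone genes than matched random lists. With a preset correlation camera called both lists, with adjusted p = 0.0066 for eIF3 and 0.015 for histones. With an estimated correlation it called neither (adjusted p = 0.611 for each). That estimate rests on 1 residual degree of freedom, so the missing calls decide nothing. Of 11 measured eIF3 subunits, 9 rose and none fell, and 6 were at least 2-fold higher in both replicates. Sms, spermine synthase, rose 24.5-fold from 4.13 in IgG, and Cetn2, a centrin of the centrosome, 23.8-fold from 2.96, where the median of the IgG array was 4.49 and no detection calls were given. Small nucleolar RNAs were at the other end, with Snora81 42.4-fold lower in the IP. In all, 2588 genes were at least 2-fold above IgG in both replicates and 868 at least 2-fold below.

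The other named genes with the largest rises over IgG were Dynlt3, a dynein light chain (20.3-fold, from 3.49), Gm4963 (18.7-fold, from 2.91), Spcs3, a signal peptidase subunit (18.0-fold), Csnk2a1, a catalytic subunit of casein kinase (17.4-fold), and Ptp4a1, a protein tyrosine phosphatase (17.2-fold). Gid4, a subunit of a ubiquitin ligase, rose 16.3-fold, Magt1 16.0-fold and Znrf2, a ubiquitin ligase, 14.7-fold. All 10 were lower in IgG than in input, with differences from -1.77 for Ptp4a1 to -4.08 for Cetn2. Cetn2 was only 0.49 higher in the IP than in input, and Csnk2a1 0.95. The 5 largest falls were Snora81 (-5.41), Snord15b (-4.49), Snord49a (-4.40), Snord47 (-4.39) and Snord49b (-4.38), all small nucleolar RNAs, which guide the modification of ribosomal RNA. These 5 were higher in IgG than in input, from 2.39 for Snord49b to 4.33 for Snora81.

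The eIF3 subunits had a median difference of 1.36 from IgG in each replicate, at percentiles 99.2 and 99.1, where matched random lists had 0.60. The largest were Eif3m, which rose by 2.97 from a low IgG value of 3.66, and Eif3e, which rose by 2.73, while Eif3c differed by 0.00 and Eif3d by 0.58, neither past the test. Adjusted over the list alone, 10 subunits rose. The same list had a median of -1.17 in IgG minus input, at percentile 5.35, where matched random lists had -0.72. After quantile normalization again it had -0.70, at percentile 1.2, where they had -0.15. In IP minus input its median was -0.09, at percentiles 47.6 and 46.7, and 0.02 after quantile normalization again. Against input 1 subunit rose, Eif3h by 1.01, and 5 fell, among them Eif3m by 1.35 on the log2 scale. Its median against IgG was 0.74 after quantile normalization again, and the list still stood apart.

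Groups of the red cell programme stood below matched random lists against IgG. Camera did not call them, with adjusted p = 0.868, 0.784 and 0.877 with an estimated correlation for heme, membrane and regulator genes, the last 2 in the upward direction. Heme biosynthesis genes had medians of -0.01 and 0.00, where random lists had 0.58. Of 12, 2 rose and 1 fell (0 and 1 adjusted over the list alone): Ppox, protoporphyrinogen oxidase, fell by 1.55, while Tmem14c (0.91), Cpox (0.63) and Urod (-0.21) did not pass. Of 27 erythroid membrane and cytoskeleton genes, with medians of 0.12 and 0.17 against 0.52, 10 rose and 6 fell (also adjusted over the list alone). Add3 rose by 2.53 and Xk by 1.87, and Kel fell by 0.71 and Tpm1 fell by 0.63. Of 27 erythroid transcription regulators, 7 rose and 5 fell (6 and 5 adjusted over the list alone). Their medians of 0.13 and 0.14, against 0.67, became a median of -0.48 after quantile normalization again. Mxi1 rose by 0.98, while Stat5b (1.14), Gfi1b (-0.70) and Lmo2 (-0.68) did not pass. After quantile normalization again the regulators still stood apart, with 1 up and 14 down, and the heme (2 and 3) and membrane (6 and 8) lists did not. In IgG minus input the regulators had a median of -0.36, at percentile 99.4, where matched random lists had -0.82. In IP minus input they stood at percentiles 75.0 and 63.6, so their position against IgG went with high values on the single IgG array. The heme and membrane lists stood at percentiles 65.7 and 59.3 in IgG minus input.

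Replication-dependent histones had medians of -0.47 and -0.45 against IgG, below all matched random lists, whose median was 0.43. Of 28, 3 rose and 9 fell (2 and 8 adjusted over the list alone), with adjusted p = 0.611 in camera with an estimated correlation. After quantile normalization again 4 rose and 18 fell, with a median of -0.84 in place of -0.43, and the list still stood apart. H2ac11 fell by 2.38 and H2bc21 rose by 1.62, while H4c9 (-1.56) and H2ac6 (1.20) did not pass.

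The other lists did not stand apart against IgG with the values as deposited. Of 34 proteasome subunits 21 rose and none fell (23 adjusted over the list alone), with Psma4 up by 3.12 and Psmc1 by 2.26. Of 65 oxidative phosphorylation genes 29 rose and 3 fell (30 and 3 adjusted over the list alone), with Atp5mpl up by 3.01 and Ndufb11 by 2.72. Of 26 translation initiation and elongation factors 13 rose and none fell (14 adjusted over the list alone), Eef1a1 by 3.08. Of 15 ubiquitin conjugation genes of red cell maturation 11 rose and 1 fell (also adjusted over the list alone), with Ube2d3 up by 2.95 and Rnf11 by 2.86. Of 46 ribosomal protein genes 12 rose and 2 fell (7 and 2 adjusted over the list alone), with Rpl27a up by 3.53, and after quantile normalization again 8 rose and 10 fell. The common-spread test had 17 ribosomal protein genes up and 12 down. For the first 4 of these lists, in the order given, that normalization gave 17, 27, 15 and 8 genes up and 5, 10, 4 and 2 down, with medians of 0.34, 0.35, 0.42 and 0.39 in place of 0.88, 0.67, 0.88 and 0.98. Camera gave these 4 adjusted p = 0.611 each with an estimated correlation.

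Among growth and RNA groups against IgG, 19 of 29 mitosis genes rose and 2 fell (20 and 2 adjusted over the list alone), Mad2l1 by 1.73 and Bub1 by 1.41 upward. Their median of 0.40 was -0.11 after quantile normalization again, with 6 up and 10 down. Of 30 DNA replication genes 13 rose and none fell (13 adjusted over the list alone), Gins1 by 1.80 and Rpa1 by 1.61, and their median of 0.38 was -0.17 after that normalization, with 6 up and 12 down. As deposited, both medians lay below those of matched random lists, 0.69 for mitosis and 0.67 for DNA replication. The mitosis list stood at percentiles 5.39 and 11.8 and the DNA replication list at 7.12 and 2.73. Of 15 mRNAs reported to carry CPE elements 6 rose and 2 fell (8 and 2 adjusted over the list alone), Bub1 by 1.41 and Cdk1 by 1.00 upward, and after that normalization 5 rose and 3 fell and their median of 0.54 became 0.10. Of 31 genes of cytoplasmic polyadenylation and deadenylation 14 rose and 2 fell (17 and 2 adjusted over the list alone), with Cnot9 up by 2.01 and Cnot6 by 1.94, while after that normalization 8 rose and 8 fell and the median went from 0.65 to 0.16. Of 27 ribosome assembly genes 14 rose (also adjusted over the list alone), Ltv1 by 1.86, and after that normalization 10 rose and 5 fell, with a median of 0.10 in place of 0.52. Of 9 ARE-binding proteins 5 rose (7 adjusted over the list alone), Celf1 by 1.22 and Tia1 by 1.18, and after that normalization 3 rose and 1 fell. In camera the ARE-binding list had adjusted p = 0.657 with an estimated correlation, and the mitosis, replication, polyadenylation and assembly lists 0.611.

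Of 26 autophagy and mitochondrial clearance genes 10 rose and 1 fell against IgG (also adjusted over the list alone): Atg4a rose by 2.93 and Atg3 by 1.86, and Ulk1 fell by 0.91. The list median of 0.30 was -0.22 after quantile normalization again, with 10 up and 9 down, and camera gave adjusted p = 0.611 with an estimated correlation. As deposited, the list stood at percentiles 10.6 and 9.32 of matched random lists, whose median was 0.55. Of 14 iron uptake and storage genes 7 rose (also adjusted over the list alone), Ireb2 by 2.80 and Ncoa4 by 1.59, and after that normalization 6 rose and 2 fell. Of 25 immediate early genes 3 rose and 7 fell (also adjusted over the list alone), and Egr3 fell by 1.11 and Dusp2 fell by 0.97. This list stood below its matched random lists after quantile normalization again, with 3 up, 14 down and a median of -0.43, and with no filter. Camera with an estimated correlation gave it adjusted p = 0.8345 and 0.823 in these 2 settings, and 0.657 in the main one. Of 4 globins 1 rose, Hbb-bh1 by 0.89, and adjusted over the list alone none did. Hbb-b1, at 11.72 in the IP, was 0.35 higher and did not pass (limma adjusted p = 0.061).

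By the limma test 4061 genes rose and 2392 fell against IgG, 62.9% upward, a share that was 51.6% after quantile normalization again (4295 and 4032). With no filter 3936 rose and 4885 fell, and with the 60th percentile filter 4041 and 927. The common-spread test called 5431 and 3106. Of the genes called by limma, 2096 differed by less than 1.5-fold, and 80.1% of genes tied between the IP replicates passed against 37.0% of the others. The common-spread test called 5 histones up and 18 down, 11 and 5 erythroid regulators, 23 and 0 polyadenylation genes, 50 and 6 oxidative phosphorylation genes and 4 and 0 globins. With a preset correlation camera called 14 lists against IgG, 13 higher, among them mitosis and DNA replication, and 1 lower, where the matched random lists set 1 higher and 4 lower, and with an estimated correlation it called none, with a smallest adjusted p = 0.611.

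Compared with input, the IP was higher in markers of blood lineages other than the red cell and of hepatocytes, and lower in genes of cell division. With a preset correlation camera called these lists, with adjusted p = 1.6e-05 for megakaryocyte markers and 5.1e-09 for DNA replication. With an estimated correlation it called none of them (adjusted p = 0.526 for each). That estimate rests on 1 residual degree of freedom, so the missing calls decide nothing. Of 12 megakaryocyte markers, 10 were at least 2-fold higher in both replicates, with a list median of 2.46. Of 30 DNA replication genes none rose and 17 fell, with a median of -1.02 in IP replicate 2. Gpnmb, a membrane glycoprotein known from macrophages, rose 33.1-fold from a low input value of 3.52, and the histone gene H2ac21 was 12.5-fold lower. In all, 562 genes were at least 2-fold above input in both replicates and 721 at least 2-fold below.

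Among the 10 genes with the largest rise over input, Gpnmb was followed by Kctd12 (17.1-fold, from 3.10), Rbpms2, an RNA-binding protein (14.8-fold), Itgb3, the platelet integrin subunit (14.7-fold), AI504432 (11.6-fold) and Alox12, the platelet lipoxygenase (11.6-fold). Timp3 rose 9.51-fold, Afp, alpha-fetoprotein, 9.37-fold from 3.93, Cybb 9.35-fold and Ngp, neutrophilic granule protein, 9.25-fold. On the IgG array Gpnmb was 3.38 above input, Ngp 2.33, Alox12 2.07, Itgb3 1.64 and Rbpms2 1.62, while AI504432 differed by -0.18. The 5 largest falls were H2ac21 (-3.64), H2ac11 (-3.23), H2ac4 (-3.18), AI450353 (-3.13) and Snord45b (-2.72). The first 3 encode histone H2A proteins.

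The megakaryocyte markers lay above all matched random lists, whose median was -0.09. Of 12, 5 rose and none fell, and 10 rose adjusted over the list alone, as 10 did over all genes after quantile normalization again. Itgb3 rose by 3.88 and Ppbp by 3.14, to values of 10.35 and 10.11 in the IP, while Gp9 (0.73) and Gp1bb (0.08) did not pass. The same markers were also higher in IgG than in input, with a median of 1.09, and against IgG their medians were 1.20 and 1.14, at percentiles 98.0 and 96.2, short of standing apart. There 6 rose (also adjusted over the list alone), Vwf by 2.84 and Itgb3 by 2.24. Camera gave the list adjusted p = 0.526 against input and 0.657 against IgG with an estimated correlation.

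Of 12 granulocyte markers 9 rose over input and none fell (10 adjusted over the list alone), with medians of 0.95 and 1.02. Ngp rose by 3.21 and Camp by 2.97, and Elane differed by 0.00. Of 11 early progenitor markers 5 rose (7 adjusted over the list alone), with medians of 0.89 and 0.88: Cd34 rose by 1.56, while Flt3 (1.34) did not pass. Of 11 hepatocyte markers 6 rose (11 adjusted over the list alone), with medians of 0.60 and 0.64. Afp rose by 3.23, and Alb, albumin, was 3.47 higher without passing (limma adjusted p = 0.0653). Of 10 macrophage markers 3 rose (also adjusted over the list alone), with medians of 0.74 and 0.62: Ctss rose by 2.27, and Adgre1 (2.90) did not pass. These 4 lists also had higher values in IgG than in input, with medians of 0.46, 0.60, 0.65 and 0.53 in the order given (0.91, 0.41, 0.58 and 0.58 after quantile normalization again), and none of them stood apart when the IP was compared with IgG. In camera each had adjusted p = 0.526 against input with an estimated correlation, and the granulocyte list 0.638 against IgG. Against IgG, 8 granulocyte, 3 early progenitor, 3 hepatocyte and 1 macrophage marker rose and 0, 2, 1 and 2 fell, with the same counts adjusted over the list alone. The common-spread test had 7, 4, 4 and 4 up and 0, 3, 0 and 2 down. After quantile normalization again 10, 7, 7 and 6 of these markers rose over input, and the counts against IgG were 6, 3, 5 and 3 up and 4, 5, 1 and 2 down.

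Endothelial and stromal markers did not stand apart against input. Of 11 endothelial markers 3 rose and none fell (3 and 1 adjusted over the list alone), with medians of 0.11 and 0.19. Stab1 rose by 1.27 and Pecam1 was 1.75 higher without passing. Of 6 stromal markers none rose or fell (none adjusted over the list alone). Against IgG 1 endothelial marker rose and 3 fell, and 1 stromal marker rose and 4 fell, with the same counts adjusted over the list alone. The common-spread test had 2 endothelial markers up and 1 down and 1 stromal marker up and 1 down against IgG. With quantile normalization again 6 endothelial markers rose and 1 fell against IgG, 1 stromal marker rose and 2 fell, and 1 endothelial marker rose over input.

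**Figure D3:**
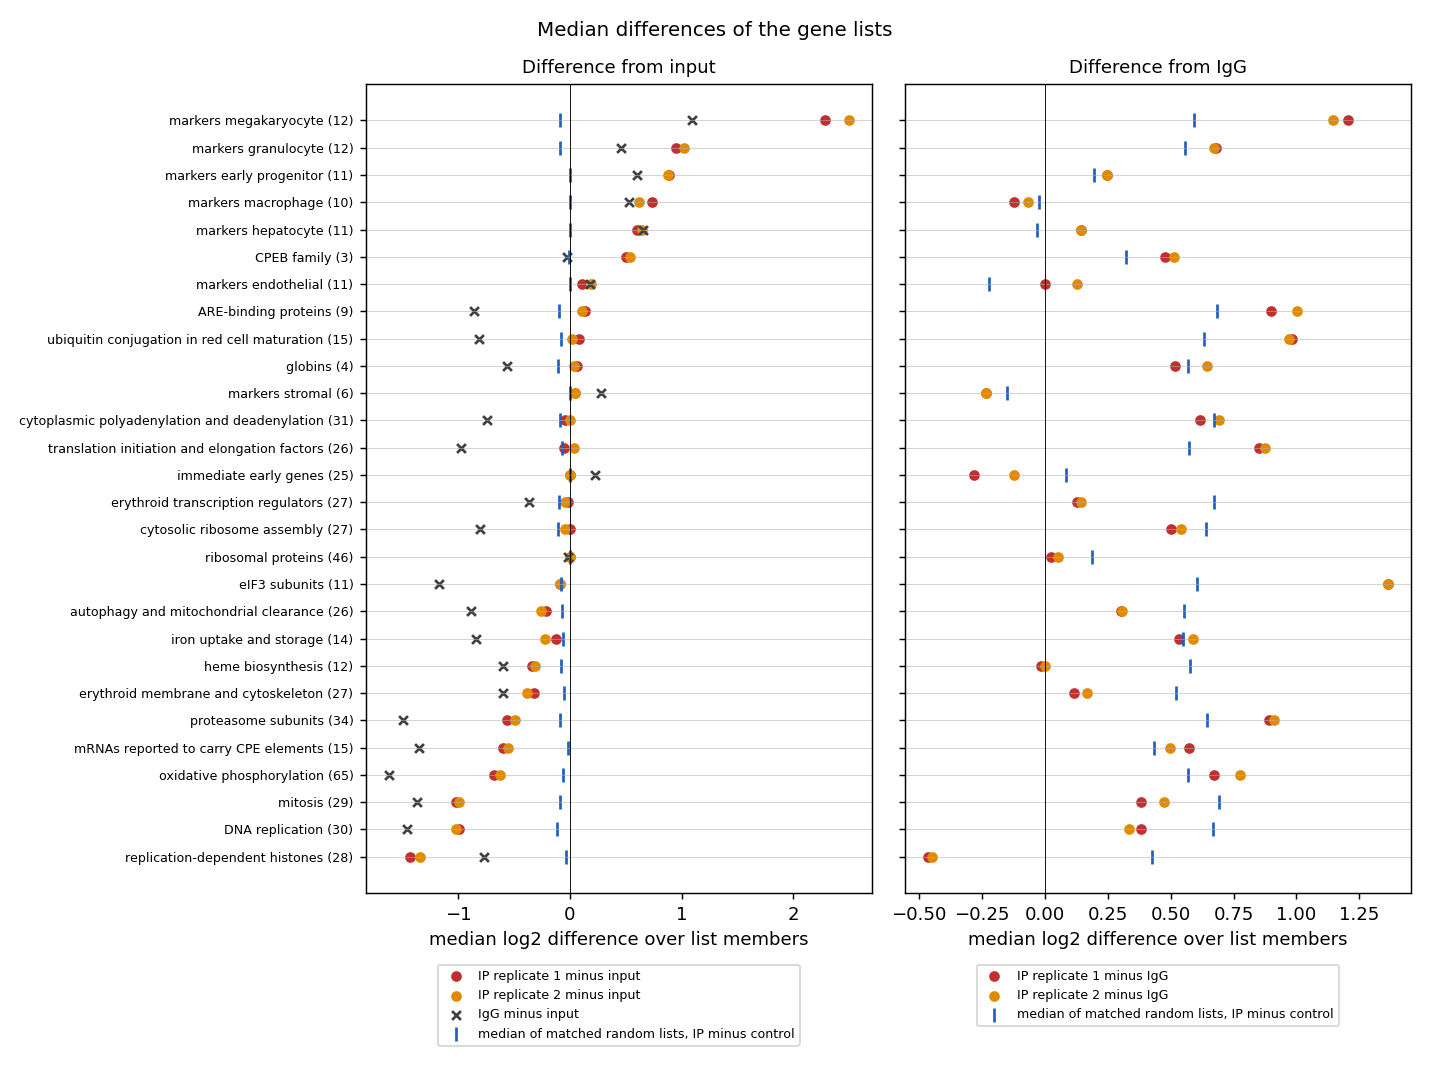
Median log2 difference over the tested members (number in parentheses) of each gene list, with IP replicates 1 and 2 minus input, and IgG minus input, on the left and the IP replicates minus IgG on the right. Bars mark the median of random lists matched on expression; the megakaryocyte markers had the highest medians against input (2.46 over both replicates) and the replication-dependent histones the lowest (-1.43 and -1.34).

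Genes of cell division were lower in the IP than in input as groups, with adjusted p = 0.526 for each of these 4 lists in camera with an estimated correlation. Of 29 mitosis genes none rose and 17 fell, with medians of -1.01 and -0.99, and 14 were at least 2-fold lower in both replicates. Adjusted over the list alone, 1 rose and 25 fell. Cdc20 (-1.86) and Ndc80 (-1.59), a kinetochore gene, were lowest and did not pass, and Cenpe (0.16) and Top2a (0.08) were highest. Adjusted over the list alone, 26 DNA replication genes fell: Cdc45 fell by 1.64, Rfc4 (-2.67) did not pass, and Rpa1 at the upper end fell by 0.45. Of 15 mRNAs reported to carry CPE elements 6 fell and none rose (10 and 2 adjusted over the list alone), with medians of -0.60 and -0.56, and several of them are mitosis genes too. Cdc20 and Aurka (-1.56) were lowest, and neither passed. Of 28 replication-dependent histones 11 fell and none rose (17 fell adjusted over the list alone), with medians of -1.43 and -1.34, below all matched random lists. Once quantile-normalised again, 22 mitosis, 17 DNA replication, 9 CPE and 18 histone genes fell and none rose.

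Oxidative phosphorylation genes had medians of -0.68 and -0.63 against input. Of 65, 1 rose and 13 fell (1 and 14 adjusted over the list alone), and 18 were at least 2-fold lower in both replicates. Atp5d fell by 2.15, Ndufa6 rose by 0.64 and Ndufs8 (-2.62) did not pass. Of 34 proteasome subunits 1 rose and 7 fell (1 and 14 adjusted over the list alone), with medians of -0.56 and -0.49: Psmd14 (-1.37) and Psmd5 (-1.32) were lowest and did not pass, and Psmb1 rose by 0.17, a call lost in the common-spread test, which had 0 up and 24 down. Camera gave both lists adjusted p = 0.526 with an estimated correlation. The IgG array also had lower medians than input in these groups, as did their matched random lists, from -0.57 for histones to -0.83 for mitosis. The medians of IgG minus input were -1.37 for mitosis, -1.46 for DNA replication, -1.35 for the CPE list, -0.77 for histones, -1.62 for oxidative phosphorylation and -1.50 for the proteasome, with histones only at percentile 15.4. Quantile normalization again moved these 6 medians to -0.64, -0.66, -0.57, -0.33, -1.07 and -0.71. Their matched random lists then had medians from -0.07 for the proteasome to -0.12 for DNA replication. In the same order, the 6 lists stood at percentiles 0.12, 0.02, 0.1, 15.4, 0 and 0.02 as deposited. After that normalization they stood at 0.12, 0.17, 0.77, 7.06, 0 and 0.03. While these groups were lower, the marker lists of megakaryocytes, granulocytes, early progenitors, hepatocytes and macrophages were higher in the same comparison.

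Red cell groups did not stand apart against input. Of 27 erythroid membrane and cytoskeleton genes 1 rose and 10 fell (2 and 17 adjusted over the list alone), with medians of -0.33 and -0.39. This list stood at percentiles 3.16 and 1.1, short of standing apart as lower. Xk rose by 0.97, while Mpp1 (-1.24) and Epb42 (-1.23) did not pass. Of 12 heme biosynthesis genes none rose and 2 fell (4 adjusted over the list alone), and the lowest, Urod (-1.54) and Uros (-1.45), did not pass. Of 27 erythroid transcription regulators 4 rose and 5 fell (7 and 9 adjusted over the list alone): Klf1, an activator of globin genes, fell by 1.71, Gata1 (-1.40) did not pass, and Myc rose by 0.90. Of 4 globins 1 fell, which is Hbb-bs and fell by 1.33, and Hbb-y, an embryonic globin, was 2.24 higher without passing (2 rose and 1 fell adjusted over the list alone). Of 14 iron genes 1 rose, Ireb2 by 0.84, and 2 fell, where Tfr2 fell by 0.88 (2 and 4 adjusted over the list alone). Of 26 autophagy genes 9 fell and none rose (14 adjusted over the list alone), and Atg4a fell by 1.16. Once quantile-normalised again, 4 autophagy and 4 heme genes fell and none rose, 6 regulators rose and 6 fell, and 2 iron genes rose and 1 fell, as for globins. With a preset correlation camera called the membrane and autophagy lists lower than input. Camera gave the membrane and autophagy lists adjusted p = 0.526 with an estimated correlation.

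Among RNA and translation groups against input, 2 of 9 ARE-binding proteins rose and none fell (also adjusted over the list alone): Zfp36 rose by 1.71 and Zfp36l1 rose 2.47-fold. Of 26 translation factors 4 rose and 2 fell (also adjusted over the list alone), with Eif4ebp2 up by 1.29 and Eef1b2 by 0.96, where the common-spread test had 8 up and 9 down. Of 31 polyadenylation and deadenylation genes 4 rose and 7 fell (also adjusted over the list alone): Pabpc1, a poly(A)-binding protein, rose by 1.01 and Pan2 fell by 1.12, and after quantile normalization again 4 rose and 3 fell. Of 15 ubiquitin conjugation genes 3 rose and 3 fell (5 and 3 adjusted over the list alone), with Ube2d1 up by 2.23 and Ube2d3 by 2.14. Of 46 ribosomal protein genes 6 rose and 2 fell (5 and 2 adjusted over the list alone), with Rpl23 up by 1.64, where the common-spread test had 12 up and 9 down. Of 25 immediate early genes 4 rose and 3 fell (6 and 3 adjusted over the list alone), and Dusp1 fell by 1.81, while after that normalization 3 rose and 4 fell. Of 27 ribosome assembly genes none rose and 5 fell (also adjusted over the list alone), and Npm1 was 1.76 higher without passing; after quantile normalization again 1 rose and 1 fell. That normalization gave 5 up and 2 down for ubiquitin conjugation genes and 3 up and 4 down for eIF3 subunits. For eIF3 subunits, 2 rose and 6 fell against input adjusted over the list alone.

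By the limma test 1306 genes rose and 1845 fell against input, and by the common-spread test 2046 and 3106. With no filter 1864 rose and 1731 fell, with the 60th percentile filter 1028 and 1904, and after quantile normalization again 1239 and 1322. Of genes tied between the IP replicates 54.0% passed the limma test, against 13.9% of the others. With an estimated correlation camera called no list against input, with a smallest adjusted p = 0.526, and with a preset correlation it called 13, 5 higher and 8 lower. The common-spread test called 1 oxidative phosphorylation gene up and 45 down, 1 and 24 histones, 1 and 7 heme genes, 5 and 7 ribosome assembly genes and 4 and 5 eIF3 subunits. The same single input array enters every one of these differences.

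IgG and input differed from each other more than the IP differed from input: over tested genes the SD of the difference was 1.03, against 0.627. At least 2-fold apart were 4432 genes, 1103 higher and 3329 lower in IgG, compared by size only, with no replicate in either arm. The highest in IgG were Cma2, a mast cell chymase gene (6.20 above input), Gm15128 (5.93), Mir680-1 (5.14), Sft2d1 (4.55) and the small nucleolar RNA Snora33 (4.55). The lowest were Gm13552 (-4.48), Mrpl32, a mitochondrial ribosomal protein (-4.47), Eif3m (-4.32), Atg4a (-4.09) and Cetn2 (-4.08). Several of these differences rest on low values: in input Cma2 had 3.07, Gm15128 2.09 and Mir680-1 3.90, and in IgG Gm13552 had 3.44, Mrpl32 2.43, Eif3m 3.66 and Cetn2 2.96. The 10th percentile was 2.43 on the input array and 2.72 on the IgG array. Cma2 also differed between the IP replicates, at 2.91 and 5.02. The median of IgG minus input ran from 0.493 in the fifth of tested genes with the lowest expression to -0.998 in the highest. The number of genes 2-fold above IgG in both IP replicates ran from 15 to 1109 over the same range.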

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

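The counts of unnamed probe sets, which carry no test, were chosen after the named genes had been compared. Probe sets without a gene name here entered no comparison above. Of 1070 such probe sets at or above the level used for named genes, 28 (2.62%) were at least 2-fold higher in both IP replicates than in IgG and in input, close to the 2.49% of tested named genes (346 of 13911). These 28 stood above both control arrays in data outside the named genes. In the opposite direction, 19 (1.78%) were at least 2-fold lower than both controls in both replicates, against 0.503% of tested named genes (70 of 13911).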

How the results depend on the processing

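The common-spread test, the 2-fold minimum beside the adjusted p, tied genes left out, control arrays left out and lists after quantile normalization were added after the result was seen. Total counts not given here stayed within 1.5 times, but not each direction: lower calls against IgG went from 2392 to 4885 with no filter, 927 with the 60th percentile filter and 4032 after quantile normalization. Without each IP replicate in turn, genes under both controls numbered 107 to 111; no test was possible there, with 0 residual degrees of freedom. At 1.5-fold the counts above IgG, above input, above both, below both and of IgG against input were 4167, 1226, 828, 219 and 7662, and at 4-fold 574, 102, 43, 13 and 891. Without the IgG array the counts over and under both became 562 and 721, without the input array 2588 and 868. With both controls as 1 group limma called 0 genes in either comparison (1112 at an unadjusted p under 0.05, smallest adjusted p 0.364). In that fit the difference between IgG and input, with an SD of 1.03 over tested genes, enters the spread. The 0 calls therefore do not speak against differences from either control alone. With a 2-fold minimum it called 2747 against IgG and 645 against input, and at an adjusted p under 0.1 4744 against input. The common-spread test called 5152 against input. For lists against IgG, camera called 14 with the preset correlation (13 higher and 1 lower), and with an estimated one 0 against IgG and 0 against input (0 at an unadjusted p under 0.05 in each).

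The correlations of ratios that share no array were 0.18 and 0.15 with no filter, 0.31 and 0.30 with the 60th percentile filter and 0.29 and 0.28 after quantile normalization again. That normalization moved the share of calls upward against IgG from 62.9% to 51.6%, and against input from 41.4% to 48.4%. It kept 266 of the 346 genes over both controls among 321. It reversed 11 differences that had passed the limma test as deposited. These were Ier3 (-0.10), Myc (-0.037), Fbxo43 (0.25), Klf1 (-0.48), Top2a (-0.000803), Atp5k (-0.28), Cul4a (-0.20), Pf4 (-0.30), Flt1 (0.089) and Spi1 (-0.58) against IgG, and Ulk1 (0.021) against input. The cause was not tested. Of these 11, Spi1, Klf1, Pf4, Atp5k and Fbxo43 passed the limma test in the opposite direction after that normalization, and the others did not pass. Of 424 named differences, 12 lost their call after that normalization, 82 gained one in the same direction and these 11 reversed. The other 319 were counted as unchanged, which can include differences that had not passed and changed sign. The common-spread test uses the same differences as limma, so it could reverse none. A median over probe sets moved nothing, with 1 probe set per gene. No paired analysis was possible because only the IP had replicate numbers. The CPE motif count was not run. The number of arrays limits the smallest difference that can be called, 0.18 against IgG and 0.19 against input with the common spread.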

Other observations

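The grouping by RNA class and every test below except the ratio of the counts above IgG and above input over both IP replicates were chosen after the result was seen.

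Of the 70 genes at least 2-fold lower in the IP than in both controls, 33 were small nucleolar or Cajal body RNAs and 7 were microRNA genes. The tested genes included 93 small nucleolar and Cajal body RNAs, many of which guide the modification of ribosomal and spliceosomal RNA. Their median difference from IgG was -2.93 (SD over genes 1.20) and from input -0.74 (SD 0.87), and 83 were at least 2-fold below IgG in both replicates. The 139 microRNA genes had a median of -1.04 against IgG and -0.07 against input, and 59 were at least 2-fold below IgG. After quantile normalization again the medians against IgG were -3.23 and -1.27, and against input -0.69 and -0.07.

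A pattern in these RNAs was the large difference between IP and IgG. Loss from the Cpeb4 IP alone is argued against on these arrays. Of the 93, 85 or 91.4% (exact binomial 95% interval 83.8 to 96.2) were higher in IgG than in input. The interval takes genes as trials, so it does not measure how precipitates vary. The narrower range of the IgG array is also argued against, since their IgG minus input median of 1.96 stood at the 100th percentile of random lists matched on expression, whose median was -0.56. The pattern has 2 parts: more of these RNAs in the IgG precipitate than in input, and fewer in the Cpeb4 precipitate. The difference of the Cpeb4 precipitate from input stood at percentile 0 in both replicates. These parts describe the same values and are no test of a cause. With 1 IgG array and 1 input array, whether another IgG precipitate would hold as many stays open, and no biological explanation was tested.

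Markers of 5 other cell types, from lists fixed before the data were examined, were higher in the IP than in input, although selection on Ter119 would remove most such cells. Fewer cells of these 5 types behind the input RNA than behind both immunoprecipitates could account for part of it but stays undecided, since 4 of the 5 lists were also above nearly all their matched random lists in IgG minus input, by the bound set for standing apart, but 2 of the 5 after quantile normalization again; Ppbp, Ngp and Alb, transcripts abundant in their own cell types, had 6.97, 6.95 and 4.24 in input, 8.96, 9.28 and 6.11 in IgG and 10.11, 10.16 and 7.70 in the IP. A lower share of every other cell type alike behind the input RNA stays undecided. The megakaryocyte median exceeded the endothelial one by 2.33 in IP minus input (bootstrap 95% interval over genes 1.29 to 2.75). In IgG minus input it did so by only 0.91 (-0.15 to 1.55), and the pair was picked after its values were seen. Both intervals take genes as replicates, so they do not measure how arrays vary. Association of these mRNAs with Cpeb4 cannot be told apart from cell makeup here, since 0 of the 5 lists stood above their random lists against IgG in both replicates, yet none lay below 0 by more than its standard error and 7 of 12 megakaryocyte markers were 2-fold over both controls. Of the 11 early progenitor genes, Gata2 and Myb are also in the erythroid regulator list.

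More genes were 2-fold above IgG than above input, 4.6 times as many. The narrower range of values on the IgG array could account for part of this: after quantile normalization of the 4 arrays again the counts were 1781 and 595, a ratio of 2.99, and 2.74 and 2.76 with IP replicate 1 or 2 alone. Set before the result was seen, the bound for this explanation was a ratio under 3; 2.99 lies nearer to it than these 3 ratios lie apart (0.25), and the spread of single control arrays is unknown, so it stays undecided. Specific association with Cpeb4 and a difference of the single IgG sample from other IgG samples stay open and were not tested.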
